A study of Mus musculus with 6 samples.

How the data were processed

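The data are RNA-seq counts from GFP-positive cells sorted by flow cytometry from the labyrinth of 6 individual mouse placentas at embryonic day 9.5. Per the labels' protocols, RNA was extracted with a column kit and treated with DNase, libraries were prepared with a kit for single-cell amounts of RNA, which amplifies cDNA, and reads were single-end and 50 bp long. Groups were taken from the genotype label, with 3 controls (1 floxed copy of Ctcf) and 3 mutants (both copies floxed), all with Tie2-cre and the mT/mG reporter. The label gives heterozygous controls, and the series' design text calls the comparison group wildtype. The genotype label was used. Each title carries its own number and no number recurs between the groups, so no pairing was possible. The labels name no litter or sequencing batch, so neither was a term in any fit. Replicates 1 to 3 are names given here within each group.

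The authors deposited 1 table of whole-number read counts per gene symbol for each library, and a table of the whole series. The submitters' processing notes name Trimmomatic, STAR 2.4.2a, HTSeq, DESeq2 and the mm10 build, without their roles. The annotation release, the trimming settings and the strand setting of the counting are not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart, and near-identical paralogs such as the globin genes carry uncertainty. The 5 summary rows that name no gene were left out of library sizes and tests. They held 32.9, 17.0 and 16.8% of reads without a feature in controls 1 to 3 and 23.8, 28.9 and 17.6% in mutants 1 to 3. Reads that aligned more than once made up 40.3, 60.5 and 60.1% in the controls and 43.6, 47.8 and 68.3% in the mutants, and reads assigned to genes 26.7, 22.4 and 22.9% and 32.4, 23.2 and 14.1%. In reads that aligned more than once, control 1 lay nearer to mutants 1 and 2 than to the other controls. Mutant 3 lay nearer to controls 2 and 3, and no fit had a term for this difference. Of the counts in genes, the 10 most abundant genes took between 18.2% (control 1) and 39.4% (mutant 3). In the deposited table of the whole series, per the file header and the values, the signal columns are the counts divided by 1 size factor per library, a log2 fold change has its standard error as a score, and p-values have an adjusted p-value. The size factors recovered from that signal equalled those of DESeq2 on the counts, with a relative deviation of at most 4.93e-10. The log2 fold changes of the deposited table are smaller in size than unshrunken ones, and its direction is mutant over control.

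Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with too few counts were removed with filterByExpr (minimum count 10, minimum total 15), which left 10269 of 38926 genes. Libraries were scaled with TMM factors, and mutants were compared with controls by the quasi-likelihood F test with robust dispersion estimates and no covariate. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The biological coefficient of variation was 0.981, and the prior degrees of freedom were 7.02. CPM are counts scaled to library size with the TMM factors, with mean and SD over 3 libraries. A gene at 0 in a whole group was given a lower bound of its fold change from a floor of 3 counts per library, between 0.299 and 0.647 CPM, and this also holds where leaving out 1 library left a group at 0. Such floors cover counting error only, since amplified reads without molecular identifiers are not independent molecules. All pairs of libraries differed by more than sampling noise (chi-square per degree of freedom of at least 52.0), so none was deposited a second time.

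A set of 26 gene lists was fixed before the data were examined, and 23 had enough tested members (at least 3) and were tested as sets. They are antioxidant and NRF2-linked genes, iron-sulfur cluster and iron handling genes, nuclear oxidative phosphorylation subunits, mitochondrially encoded genes, mitochondrial and cytosolic ribosomal proteins, endothelial identity genes, arteriovenous, Notch and sprouting genes, p53 targets, S-phase genes, G2 and M-phase genes, stress response genes, glycolysis and hypoxia genes, interferon genes, imprinted genes, Hox genes, cohesin partners, markers of erythroid, macrophage, megakaryocyte, trophoblast and mesenchymal cells, and immediate early genes. Clustered protocadherins (1 tested), yolk sac endoderm genes (0 tested) and sex-linked genes were not tested as sets. Lists were tested with camera on log2 CPM with a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists. Members were also adjusted over the list alone. List pairs shared at most 1 tested gene, Dlk1 in the case of the imprinted and mesenchyme lists.

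Genes named in the text follow a rule set in advance. It takes Ctcf, then up to 12 genes per direction with the largest change among those that pass with a mean CPM of at least 5 and no overlap between groups, leaving out predicted genes. Where fewer than 5 pass in a direction, the 5 with the smallest p are given as values. It adds up to 4 members of each list with the smallest adjusted p, or the highest mean CPM for lists of other cell types, and Fxn and sex-linked genes. Genes outside the rule are said to be chosen after their values were seen.

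Alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1) with and without sample quality weights, RLE, upper quartile and no scaling factors, no filter on low counts or a mean CPM of at least 5, a fit without robust dispersions, embryo sex as a term, removal of globin, mitochondrially encoded and ribosomal RNA genes, thresholds of 0.1 and 0.01, and leaving out each replicate in turn. Fits with a mesenchyme or erythroid score as a term were added after the data had been seen. The tests were tried on simulated counts with 200 changed genes before use. Gene positions and transcript lengths come from GENCODE mouse release M21 on the same build, in which 99.36% of the tested genes had a match by current or older symbol. DESeq2 left 5683 genes without an adjusted p, and these were not counted as lost calls.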

Results

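RNA was sequenced from GFP-positive cells sorted from the placental labyrinth of 6 individual mouse embryos at embryonic day 9.5, the stage at which the labyrinth becomes the site of exchange between mother and embryo. The cells carried the mT/mG reporter at the Rosa locus, which switches from a red to a green membrane protein in cells that have expressed Cre and in their descendants. Cre was driven by Tie2, a promoter active in endothelial cells and also in blood-forming cells. In 3 mutant embryos both copies of Ctcf were floxed. In 3 control embryos 1 copy was floxed and the other was not, so the controls were heterozygous deletions with the same Cre, not embryos without Cre. The study asked how loss of CTCF, the zinc-finger protein that binds insulators and shapes chromatin loops, alters transcription in endothelial cells, and its title names oxidative stress. Each library came from its own embryo, so the replicates are biological. The control libraries held 8971244, 8824007 and 9528211 counts in genes (replicates 1 to 3) and the mutant libraries 7522092, 6513258 and 5227516. Between 11818 and 12320 genes were detected in the controls, against 10480, 11943 and 10320 in the mutants. Rank correlations between libraries were 0.834 to 0.892 within the controls, 0.636 to 0.732 within the mutants and 0.629 to 0.779 between the groups, so the mutants differed from one another about as much as from the controls. By Xist and Y-linked genes, 2 controls and 1 mutant were female and the other embryos were male, though mutant 2, taken as female, also held Y-linked reads (15 CPM) and mutant 3, taken as male, Xist reads (20.5 CPM).

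Ctcf itself (chromosome 8, 105636568 to 105682922, plus strand, mm10) was measured at 143, 150 and 211 CPM in controls 1 to 3 and at 0, 18.1 and 3.45 CPM in mutants 1 to 3. The means were 168 ± 37.3 CPM in controls and 7.19 ± 9.63 CPM in mutants (SD, n = 3), a log2 fold change of −4.54 (SE 1.17), and every mutant lay below every control. The labels and the counts therefore go the same way in all 6 libraries. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment over 10269 genes, the difference did not pass the threshold (adjusted p = 0.203). DESeq2 gave a log2 fold change of −4.49 with an adjusted p of 0.00445. The exons removed by Cre are not given in the sources used here, so the counts can include reads from exons left in place. Reads carried over from other libraries, or from other cells, were not tested as a source of the Ctcf counts in mutant 2.

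Zmat3, a p53 target that encodes an RNA-binding zinc-finger protein, was the one gene that passed the edgeR threshold. It rose from 6.09 ± 3.48 CPM in controls to 170 ± 45.2 CPM in mutants (SD, n = 3), 27.9-fold (log2 fold change 4.80, SE 0.56, adjusted p = 0.0349), in 3 of 3 mutants. It lies on chromosome 3 from 32334792 to 32366014 on the minus strand. The call was lost without control replicate 1 (adjusted p = 0.0653), control replicate 3 (0.114), mutant replicate 2 (0.156) or mutant replicate 3 (0.0763), and with limma-voom (0.0666), which called 69 other genes, while the fold change in the fits without 1 library stayed between 4.51 and 5.35 on the log2 scale. No gene passed in the lower direction by edgeR, while DESeq2 called 219 lower and 342 higher. At an unadjusted p under 0.05, 484 genes were higher and 550 lower, and at an adjusted p under 0.1 the counts were 28 and 6. The groups did not overlap for 2058 genes (818 higher and 1240 lower), 20.0% of those tested, where random labels give 10% on average. Genes vary together and the share was not computed for other splits of the libraries, so this excess was not tested. More tested genes were also at 0 in each mutant than in each control.

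The genes with the next smallest p-values did not pass by edgeR and are given as values, though DESeq2 called each of the 9 named here. In the higher direction, fibronectin (Fn1), an extracellular matrix protein, was at 832 ± 240 CPM in controls and 3326 ± 565 CPM in mutants. Atf5, a transcription factor of the integrated stress response, was at 14.0 ± 9.70 and 264 ± 57.0 CPM. The cardiac troponin gene Tnni3 was at 1.19 ± 0.964 and 65.9 ± 10.3 CPM. Ccdc136 was at 0 CPM in the 3 controls and at 47.4 ± 10.7 CPM in mutants, at least 141-fold higher when the floor of 3 counts per library stands for the controls. Each of these 4 had an adjusted p of 0.0712. In the lower direction, the transferrin receptor Tfrc, which takes up iron, was at 1586 ± 289 CPM in controls and 383 ± 96.5 CPM in mutants (adjusted p = 0.0712). The ribosome-binding membrane protein gene Lrrc59 was at 258 ± 17.1 and 71.3 ± 12 CPM, and the arrestin gene Arrb1 at 992 ± 104 and 317 ± 84.0 CPM. Nsmce4a, of the SMC5/6 complex, was at 102 ± 13.5 and 15.3 ± 5.24 CPM, and Tmem56 at 232 ± 45.4 and 57.0 ± 18.4 CPM. The edgeR adjusted p of these 4 lay between 0.0937 and 0.0975.

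**Figure D1:**
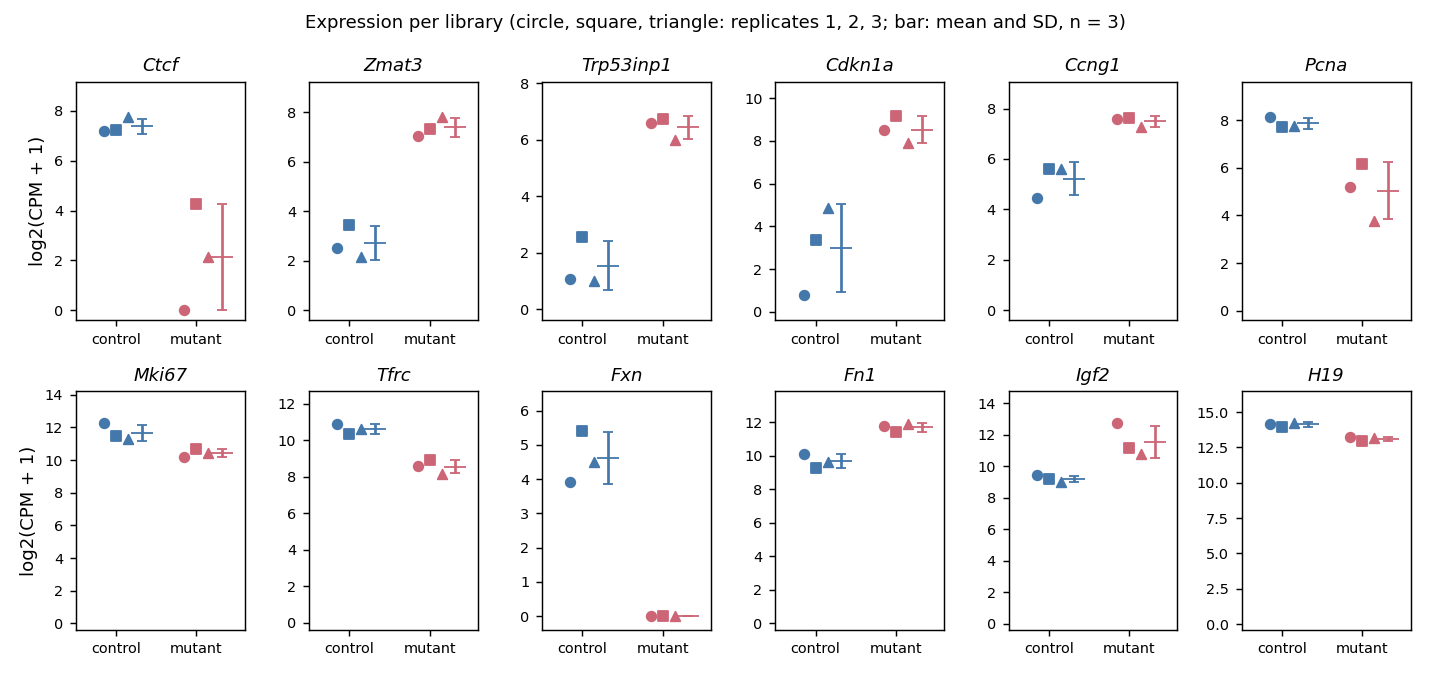
CPM of 12 genes in each library, as log2(CPM + 1), for 3 controls (blue) and 3 mutants (red), with circles, squares and triangles for replicates 1, 2 and 3 and bars for the mean and SD (n = 3). Ctcf was at 18.1 CPM or less in the mutants, Fxn was at 0 in all 3, and every mutant lay above every control for Zmat3, Trp53inp1, Cdkn1a and Ccng1.

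Targets of p53, the factor that halts the cycle or triggers death after DNA damage, rose as a group in the mutants. Of 26 list members tested, 18 had a fold change above 0 and 8 below 0. Adjusted over the list alone, 5 were higher and none lower, and 1 passed over all genes by edgeR (5 higher and 1 lower by DESeq2). Beside Zmat3, these were Trp53inp1 (2.33 ± 2.22 to 88.1 ± 22.9 CPM), the cyclin-dependent kinase inhibitor Cdkn1a (12.6 ± 13.9 to 393 ± 168 CPM), the cyclin gene Ccng1 (38.7 ± 15.4 to 180 ± 25.4 CPM) and the death gene Bbc3 (7.43 ± 4.48 to 59.4 ± 13.9 CPM), the last named after its values were seen. In each, every mutant lay above every control. Without control replicate 3 the log2 fold change of Cdkn1a went from 4.96 to 6.30, and without control replicate 2 that of Trp53inp1 from 5.24 to 6.36. The list's median log2 fold change was 0.51, and camera with a preset correlation of 0.01 placed the list higher than other genes (adjusted p = 6.52e-05). Its adjusted p with an estimated correlation was 0.105. Mesenchyme genes were also higher in the mutants, by 1.5 on the log2 scale in their mean score (SE 0.29).

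Genes of DNA replication and mitosis fell together. Of 29 S-phase genes, 11 were lower and 0 higher when adjusted over the list alone, with a median log2 fold change of −1.21 (camera adjusted p = 1.64e-10). The adjusted p with an estimated correlation was 0.105. With the preset correlation the S-phase list also passed in some splits that mix the genotypes (lowest camera adjusted p = 4.12e-05). Among those 11 were the ribonucleotide reductase subunit Rrm2 (167 ± 38.5 to 50.1 ± 5.50 CPM), the replication clamp Pcna (234 ± 39.9 to 39.5 ± 28.8 CPM) and the helicase subunits Mcm5 (493 ± 106 to 169 ± 65.5 CPM) and Mcm7 (225 ± 24.4 to 87.5 ± 29.6 CPM). Pcna went from −2.56 to −3.25 on the log2 scale without mutant replicate 2. Of 30 G2 and M-phase genes, 4 were lower and 0 higher over the list alone, and all 30 had a fold change below 0 (median −0.86, camera adjusted p = 1.08e-08). Their adjusted p was 0.173 with an estimated correlation. These 4 were Mki67 (3432 ± 1236 to 1385 ± 227 CPM), Hmmr (242 ± 48.0 to 92.0 ± 30.9 CPM), the checkpoint kinase Bub1b (311 ± 95.2 to 125 ± 27.6 CPM) and Nusap1 (84.7 ± 15.8 to 21.3 ± 10.1 CPM). No member of either list passed over all genes by edgeR, while DESeq2 called 5 S-phase and 4 G2 and M-phase genes lower, among them the 8 named. The erythroid genes, whose cells divide at this stage, were also lower as a list (mean score difference −0.74, SE 0.17).

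Imprinted genes, many of them controlled through CTCF binding sites, were mostly higher. Of 30 tested, 12 were higher and 2 lower when adjusted over the list alone, and none passed over all genes by edgeR, where DESeq2 called 9 higher and 1 lower (median log2 fold change 1.49, camera adjusted p = 2.86e-09). The list's adjusted p was 0.163 with an estimated correlation. With the preset correlation the imprinted list also passed in splits of the libraries that mix the genotypes (lowest camera adjusted p = 1.81e-06). The growth factor gene Igf2 rose from 587 ± 84.6 to 3582 ± 2749 CPM, and its clearance receptor Igf2r from 292 ± 39.6 to 857 ± 147 CPM. The adaptor gene Grb10 rose from 780 ± 111 to 2417 ± 460 CPM and the Notch-related Dlk1 from 102 ± 20.2 to 517 ± 377 CPM. Mutant replicate 1 drove part of this, since without it Igf2 went from 2.61 to 1.77 and Dlk1 from 2.34 to 1.56 on the log2 scale. The 2 that fell, named after their values were seen, were H19, the noncoding RNA that shares a CTCF-bound control region with Igf2 (18003 ± 1912 to 8855 ± 829 CPM), and the cell cycle inhibitor Cdkn1c (284 ± 148 to 110 ± 40.8 CPM). On chromosome 7, H19 spans 142575529 to 142578143 and Igf2 142650766 to 142666816, both on the minus strand. The mesenchyme list, with which it shares Dlk1, rose in the same libraries. Other groups tied to CTCF did not pass camera, though the Hox list did in some settings. The 5 Hox genes tested had a median of 2.4 (adjusted p = 0.0568), at low levels such as 0.499 ± 0.863 and 18.2 ± 14.9 CPM for Hoxd8. The Hox list passed without control replicate 1 (median 1.41, adjusted p = 0.0215), control replicate 3 (2.05, 0.0418) or mutant replicate 1 (1.36, 0.0370) and without a low count filter (1.59 with members at 0 at their bound, 0.0346), while its median was 0.72 without mutant replicate 2, 0.87 without mutant replicate 3 and 4.22 with embryo sex as a term. The 19 cohesin and CTCF partner genes had a median of −0.44 (adjusted p = 0.152), with Rad21, a cohesin subunit, at 444 ± 40.8 and 257 ± 66.7 CPM. Of the clustered protocadherins, Pcdhga9 was the single one tested, at 36.4 ± 10.4 and 83.4 ± 62.1 CPM (adjusted p = 0.604).

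The endothelial identity list stood slightly higher than other genes in the mutants (26 tested, median 0.61, camera adjusted p = 0.0376). An estimated correlation gave an adjusted p of 0.485. The list did not pass without control replicate 1 (median 0.26, adjusted p = 0.309), mutant replicate 1 (0.58, 0.116) or mutant replicate 3 (0.34, 0.232), with embryo sex as a term (0.20, 0.245) or with a mean CPM of at least 5 (0.61, 0.0702). Its one member past the threshold over the list alone went the other way. This was Tal1, a factor of blood and endothelial progenitors, which fell from 390 ± 35.2 to 170 ± 26.4 CPM. The sorts held much erythroid RNA. Globin genes took 6.74, 12.5 and 11.7% of counts in controls 1 to 3 and 13.1, 9.67 and 7.78% in mutants 1 to 3. The median member level in controls was 425 CPM for erythroid genes and 26.0 CPM for endothelial genes. Changes such as those of Tal1 and Tfrc therefore cannot be assigned to endothelial cells from these counts. The receptors Tek and Kdr did not pass by edgeR, though DESeq2 called Tek higher just under the threshold, at 27.2 ± 7.06 and 117 ± 107 CPM, and at 95.1 ± 22.3 and 195 ± 88.7 CPM. Arteriovenous, Notch and sprouting genes rose as a list (24 tested, median 0.95, camera adjusted p = 0.000217). With an estimated correlation the adjusted p was 0.163, and without mutant replicate 3 it was 0.0534. Notch1 rose from 22.9 ± 1.96 to 138 ± 83.1 CPM and the receptor Nrp2 from 43.5 ± 20.3 to 169 ± 60.4 CPM, the 2 that passed over the list alone. Flt4 (12.5 ± 5.98 and 47.8 ± 6.07 CPM) and the gap junction gene Gja1 (7.68 ± 7.45 and 45.7 ± 6.6 CPM) did not, though DESeq2 called Flt4 higher (adjusted p = 0.0371).

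For the oxidative stress named in the title, antioxidant and NRF2-linked genes did not pass camera as a list (34 tested, 20 above and 14 below 0, median 0.14, camera adjusted p = 0.152). None passed over the list alone by edgeR, and at an unadjusted p under 0.05, 6 were higher and 3 lower. Fry's test for change in either direction did pass (adjusted p = 0.00371), as it did for other lists such as the S-phase (0.00338) and erythroid lists (0.00371). Of the antioxidant genes DESeq2 called 3 over all genes, Glrx lower (adjusted p = 0.000221) and Gsto1 and Prdx6 higher (0.0417 and 0.0355). The antioxidant list passed camera, in the higher direction, without control replicate 2 (median 0.20, adjusted p = 0.0495) or mutant replicate 1 (0.50, 0.0156). Without mutant replicate 3 its median was −0.044. Glutaredoxin (Glrx) was at 14.2 ± 6.37 CPM in controls and at 0 in the 3 mutants, at least 29.3-fold lower by the floor of 3 counts per library. Gpx1, a peroxidase, was at 1103 ± 495 and 482 ± 97.5 CPM. Gsto1 (37.9 ± 19 and 108 ± 4.12 CPM) and Prdx6 (297 ± 93.1 and 570 ± 42.7 CPM) lay higher in every mutant than in every control. Among 30 genes of iron-sulfur clusters and iron handling, 2 fell when adjusted over the list alone, Tfrc and frataxin (Fxn), the mitochondrial protein of iron-sulfur cluster assembly. Fxn (chromosome 19, 24261453 to 24280605, minus strand) was at 14.2, 41.7 and 21.7 CPM in controls 1 to 3 and at 0 in the 3 mutants, at least 53.5-fold lower by the same floor. Its edgeR adjusted p was 0.163 over all genes and 0.0190 over the list alone. The study is known to have followed up Fxn, which it chose on these samples, so the count over this list is not independent evidence. The list as a set did not pass camera (median −0.03, mean −0.54, camera adjusted p = 0.173). Fry's test for change in either direction passed (adjusted p = 0.00417), with Fxn among the members. Slc11a2, an iron transporter, was at 181 ± 31.9 and 79.8 ± 55.1 CPM, and Glrx5 at 595 ± 159 and 353 ± 195 CPM.

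Of the energy and ribosome lists 1 passed. Cytosolic ribosomal protein genes fell slightly as a list (76 tested, median −0.55, camera adjusted p = 0.0254), with Rplp0 at 388 ± 129 and 176 ± 45.9 CPM, and no member passed. Its adjusted p with an estimated correlation was 0.377, and the list did not pass without control replicate 2 (0.165), control replicate 3 (0.0619) or mutant replicate 2 (0.113). The 75 nuclear oxidative phosphorylation subunits had a median of −0.27 (adjusted p = 0.152), with Uqcrc1 at 170 ± 23.4 and 59.5 ± 27.5 CPM and Cox7a2 at 57.9 ± 15.1 and 13.9 ± 2.55 CPM. The 7 mitochondrially encoded genes had a median of −0.61 (adjusted p = 0.0906), with mt-Co1 at 4790 ± 2824 and 1662 ± 322 CPM. The 73 mitochondrial ribosomal protein genes had a median of −0.44 (adjusted p = 0.0990), with Mrps2 at 39.7 ± 10.6 and 4.34 ± 6.01 CPM. No member of these 3 lists passed over the list alone by edgeR, while DESeq2 called 2 oxidative phosphorylation genes lower, Cox7a2 among them (adjusted p = 0.00993). The list medians and calls depend on single libraries. Without control 1 the oxidative phosphorylation (adjusted p = 0.000308), mitochondrially encoded (6.25e-05) and mitochondrial ribosomal (0.00366) lists passed in the lower direction, as they did with embryo sex as a term (0.0223, 0.00597 and 0.0378), and the last 2 also without a low count filter (0.0356 and 0.0155). Without control 2 the 3 medians were −0.12, −0.38 and −0.18 (adjusted p of 0.932, 0.602 and 0.435), and without mutant 3 the oxidative phosphorylation median was −0.49 (0.133). Control 1 had a score of 4.87 for the oxidative phosphorylation list, below the 5.07 to 5.25 of the mutants, and of 9.11 for the mitochondrially encoded genes, below their 9.46 to 9.74. For the mitochondrial ribosomal list it lay within them (3.91 against 3.66 to 4.07). The libraries also differed in mitochondrial rRNA, at 1.15, 5.71 and 5.9% of counts in controls 1 to 3 and 0.422, 0.846 and 1.54% in mutants 1 to 3, and in all rRNA-like genes, at 7.02, 21.8 and 18.5% and 8.86, 10.6 and 29.2%. In the rRNA-like share control 1 lay nearer to mutants 1 and 2 than to the other controls.

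Unfolded protein and integrated stress response genes rose as a list (26 tested, median 0.37, camera adjusted p = 0.000943), with 1 member, Atf5, past the threshold over the list alone. An estimated correlation gave an adjusted p of 0.105. Glycolysis and hypoxia genes did not pass as a list (28 tested, median 0.29, camera adjusted p = 0.0747). They passed without control replicate 3 (0.0370), mutant replicate 1 (0.00506) or mutant replicate 2 (0.0356) and without a low count filter (0.0331), and without mutant replicate 3 their median was −0.16. Ndrg1, a hypoxia-induced gene, was the member that rose over the list alone (28 ± 6.18 to 181 ± 112 CPM). P4ha2 was at 16.3 ± 9.47 and 87.2 ± 53.7 CPM, called higher by DESeq2 (adjusted p = 0.0177). Interferon and inflammation genes did not pass (14 tested, median 0.32, mean 0.11, while camera's direction was lower, adjusted p = 0.979), with Bst2 at 13.4 ± 5.55 and 28.2 ± 13.8 CPM. Immediate early and dissociation stress genes, a sign of handling, did not pass (24 tested, median 0.29, camera adjusted p = 0.126), except without mutant replicate 3 (0.0482) or a low count filter (0.0350). Egr1 was at 50.2 ± 19.9 and 198 ± 137 CPM and Jun at 76.2 ± 8.07 and 188 ± 129 CPM, while Ier3 was at 15.4 ± 7.16 CPM in controls and 0 in the mutants; of these DESeq2 called Egr1 higher and Ier3 lower (adjusted p of 0.0288 and 0.000113).

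Markers of other cell types also differed between the mutant and control sorts. Fry's directional test asks whether members move on balance one way. It gave adjusted p-values of 0.0355 for the S-phase list and 0.0213 for the Hox list. For the p53, G2 and M-phase, stress response, erythroid and mesenchyme lists it gave 0.0493. Lists that passed camera did not all pass this test, with 0.0815 for the macrophage and trophoblast lists, 0.0959 for the arteriovenous and 0.123 for the imprinted list. It gave 0.126 for the cytosolic ribosomal and 0.473 for the endothelial list. Mesenchyme and mural genes rose (16 tested, 8 higher and 0 lower over the list alone, median 1.79, camera adjusted p = 3.31e-08). The list's adjusted p was 0.105 with an estimated correlation. With the preset correlation the mesenchyme list also passed in some splits that mix the genotypes (lowest camera adjusted p = 5.68e-05). The collagens Col1a1 (694 ± 816 to 3108 ± 1573 CPM), Col3a1 (480 ± 433 to 1589 ± 928 CPM) and Col1a2 (278 ± 312 to 1064 ± 552 CPM) were among the 8, as was Postn (89.1 ± 128 to 705 ± 767 CPM). None of these named genes passed over all genes by edgeR or by DESeq2 (DESeq2 adjusted p between 0.0800 and 0.262), while DESeq2 called 3 other members higher. Control 1 stood apart, with Col1a1 at 1629 CPM against 132 and 320 in the other controls. Without it the log2 fold change went from 2.16 to 3.79 for Col1a1, from 1.73 to 2.74 for Col3a1, from 1.94 to 3.42 for Col1a2 and from 2.98 to 5.54 for Postn, and without mutant replicate 1 Col3a1 was at 1.14 and Postn at 1.57. Trophoblast genes rose as a list (7 tested, 5 above and 2 below 0, median 2.06, camera adjusted p = 0.000943). Hand1 (4.57 ± 5.33 to 160 ± 131 CPM) and Krt18 (0.293 ± 0.507 to 52.5 ± 40.2 CPM) passed over the list alone. Slc16a1, the most abundant member tested, went the other way (116 ± 17.7 and 63.7 ± 39.4 CPM), and Tfeb was at 12.2 ± 7.93 and 23.5 ± 8.51 CPM. Neither of these passed by edgeR or DESeq2. With an estimated correlation the list's adjusted p was 0.163. The list's median was 4.10 without control replicate 2, with members at 0 in a group set at their bound, and 2.79 without control replicate 1. Hand1 went from 5.11 to 6.63 without control replicate 1 and to 4.23 without mutant replicate 1. Krt18 went from 7.46 to 6.88 without control replicate 1 and 6.63 without mutant replicate 1, and without control replicate 2, where the controls left were at 0, it was at least 165-fold higher. Erythroid genes fell (21 tested, 5 lower over the list alone, median −0.81, camera adjusted p = 0.000943). Its adjusted p with an estimated correlation was 0.217. The embryonic globin Hbb-bh1 fell from 16059 ± 7970 to 4445 ± 1081 CPM, whereas Hbb-y (67778 ± 25871 and 58493 ± 19272 CPM), Hba-x (23253 ± 8905 and 36688 ± 5109 CPM) and the anion exchanger Slc4a1 (4512 ± 65.1 and 3275 ± 1027 CPM) did not pass. Macrophage and leukocyte genes fell (18 tested, median −1.35, camera adjusted p = 0.000766). An estimated correlation gave an adjusted p of 0.261, and the median was −2.49 without mutant replicate 2, with members at 0 in a group at their bound, and −2.38 with embryo sex as a term. The 2 that passed over the list alone were the mannose receptor Mrc1 (41.2 ± 19.2 to 0.190 ± 0.330 CPM; −7.59 on the log2 scale, −6.97 without mutant replicate 1, and at least 79.9-fold lower without mutant replicate 2, where the mutants left were at 0) and, named after its values were seen, myeloperoxidase (Mpo), at 20.7 ± 7.54 CPM in controls and 0 in the mutants, at least 42.8-fold lower. Runx1, of blood progenitors, was at 41.1 ± 11.9 and 38.2 ± 24.6 CPM. Megakaryocyte genes did not pass as a list (7 tested, median −2.37, camera adjusted p = 0.152). They passed without control replicate 1 (median −2.80, adjusted p = 0.00403), mutant replicate 1 (−2.49, 0.0323) or mutant replicate 2 (−2.90, 0.0107) and without a low count filter (−2.45, 0.00492), while the median was −1.69 without control replicate 2 and −1.57 with a mean CPM of at least 5, each with members at 0 in a group at their bound. Single members went both ways, with Itga2b at 149 ± 47.5 and 315 ± 149 CPM and Plek at 77.2 ± 4.96 and 14.8 ± 17.3 CPM. No yolk sac endoderm gene was high enough to be tested.

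**Figure D2:**
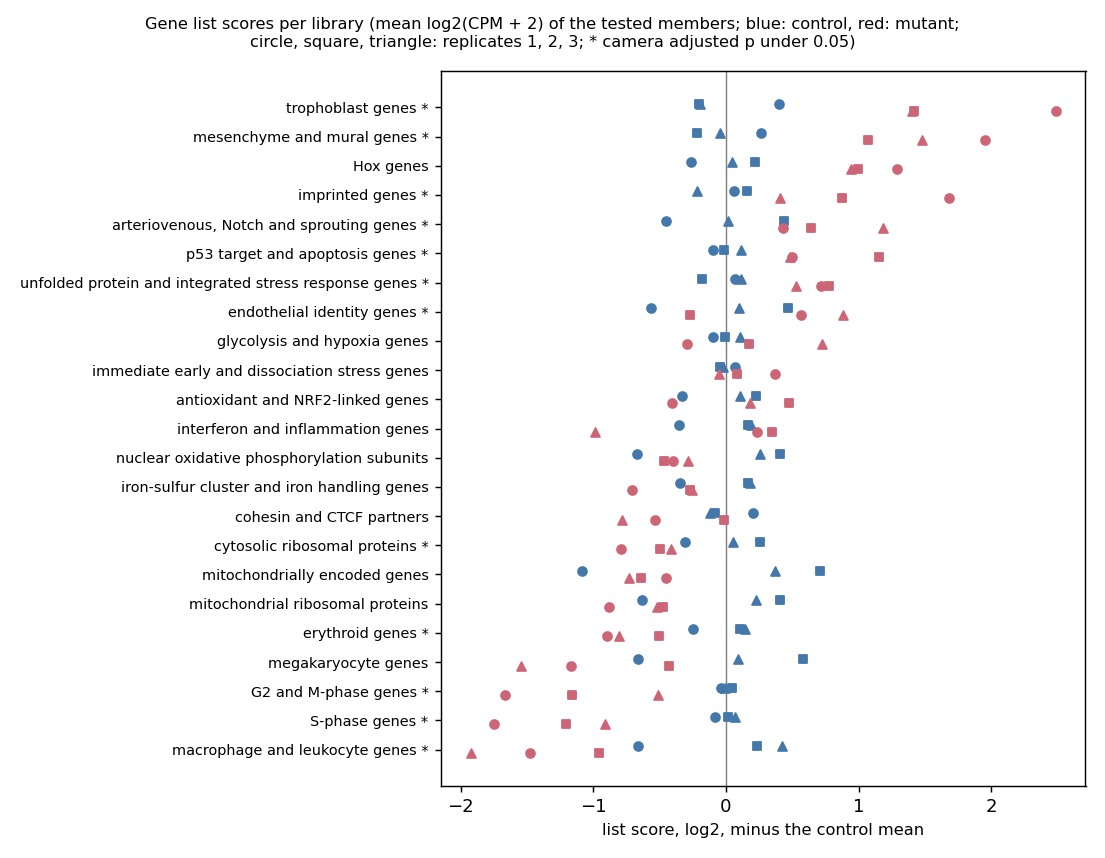
Score of each gene list in each library, as the mean log2(CPM + 2) of its tested members minus the mean of the 3 controls, for 3 controls (blue) and 3 mutants (red). Before the control mean was subtracted, the S-phase scores lay between 5.16 and 5.99 in the mutants and 6.82 and 6.98 in the controls. The mesenchyme scores before subtraction lay between 5.76 and 6.63 against 4.46 to 4.94.

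In the authors' deposited table, 387 of 9750 genes with an adjusted p passed 0.05, 232 higher and 155 lower. DESeq2 run on the same counts called 561, 342 higher and 219 lower, and all 387 were among them with the same sign. The authors' deposited table gave Fxn a log2 fold change of −4.74 (adjusted p = 1.75e-07) and Ctcf one of −2.84 (adjusted p = 0.00851). The deposited fold changes were smaller in size than those of DESeq2 here, with a median absolute value of 2.04 against 2.39 over the same genes. Of the 561 DESeq2 calls, 455 were tested by edgeR with a p under 0.05 before adjustment. A count of 0 in at least 1 library was found in 41.0% of the 561 calls and in 28.1% of the genes tested by edgeR. DESeq2 filters genes in another way, so these shares do not rest on the same genes. A single set of counts over 10269 genes was simulated from edgeR's dispersion estimates, with independent genes and the same spread in both groups. In it edgeR recovered 9 of 100 genes changed 4-fold and 41 of 100 changed 16-fold with 2 false calls. DESeq2 recovered 25 and 61 with 66 false calls, and limma-voom 10 and 29 with 3. In this simulation, most changes of 4-fold went undetected by each of the 3 tools. The real mutants were less alike (rank correlations of 0.636 to 0.732) than the controls (0.834 to 0.892), and the simulated counts follow edgeR's own model. The false calls therefore do not measure the error among the real DESeq2 calls.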

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

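No result met the rules set for this part. Groups of 3 libraries are too small for the test of single outlying samples, the design has 1 contrast, and all 6 libraries entered the comparison, with the 10269 genes that passed the count filter.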

How the results depend on the processing

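The fits with a cell-type score as a term, and the tests of other sample splits, were chosen after the data had been seen, and the other settings before. Zmat3 kept its direction in all 17 planned settings and its call in 12. The edgeR total stayed at 1 gene with RLE, upper quartile or no scaling factors, a mean CPM of at least 5, non-robust dispersions, or without dominant genes. DESeq2 called 561 genes (342 higher, 219 lower), limma-voom 69 (40 and 29), limma-voom with quality weights 139 (103 and 36), and edgeR without a low count filter, over 16772 genes, 191 (127 and 64). The cause was not tested. On a single set of counts simulated with no change, from edgeR's dispersions and with the same spread in both groups, DESeq2 made 36 calls, edgeR 2 and limma-voom 0. With embryo sex as a term 2 genes passed, both higher. An adjusted p under 0.1 gave 34 (28 higher, 6 lower) and one under 0.01 gave 0. Leaving out 1 library gave between 0 and 3 genes, all higher, with 0 without control replicate 1 or 3 or mutant replicate 2 or 3, 2 without mutant replicate 1 and 3 without control replicate 2. Ctcf in mutant versus control stayed between −6.80 and −3.94 on the log2 scale in the planned settings and passed in one, DESeq2 (−4.49, adjusted p = 0.00445). Of the 23 lists, 12 passed camera with the preset correlation, between 11 and 18 in the other planned settings, and 0 with an estimated correlation. On counts simulated at this size with independent genes, camera with that setting detected a set of 30 genes raised 2-fold (unadjusted p of 0.00256) and not an unchanged set (0.279). Estimated correlations in the real data were 0.21 for the G2 and M-phase, 0.19 for the imprinted and 0.020 for the p53 list. The simulation therefore does not show the power of that setting on correlated lists. The S-phase, G2 and M-phase, p53, imprinted, mesenchyme, trophoblast, erythroid, macrophage and stress response lists passed in all 14 preset-correlation settings, the arteriovenous list in 13, the cytosolic ribosomal list in 11 and the endothelial list in 9. Of the lists that did not pass, the Hox, glycolysis and megakaryocyte lists passed in 4 of these settings, the mitochondrial ribosomal and mitochondrially encoded lists in 3, and the antioxidant, oxidative phosphorylation and immediate early lists in 2. With the mesenchyme score as a term 0 genes and 2 lists passed (p53 and antioxidant, adjusted p = 0.00319 and 0.0126), and Ctcf turned to 0.81. With the erythroid score 0 genes and 5 lists passed (p53, S-phase, G2 and M-phase, arteriovenous and antioxidant). Neither score overlaps between the groups, so these fits cannot separate score from genotype. Camera's direction for the interferon list, which passed in no setting, turned higher without a low count filter (median 0.37), with a mean CPM of at least 5 (0.32), with embryo sex as a term (0.31) and without control replicate 1 or 3 or mutant replicate 3; its median over the fits without 1 library ran from 0.021 to 0.77, and the cause was not tested. Of the genes that never passed, Nprl3 turned to 0.045 and Runx1 to 0.13 with quality weights, and over the fits without 1 library Nprl3 ran from −0.24 to 0.091, Runx1 from −0.76 to 0.17 and Snrnp25 from −0.79 to 0.057. The median log2 fold change of all genes was −0.049 with edgeR, −0.33 with limma-voom and −0.30 with quality weights, and no other planned setting moved it by over 0.1. Over the genes named, Ctcf and the sex-linked genes apart, 1208 gene and setting pairs kept direction and side of the threshold, 151 gained a call, 5 lost one and 8 turned. Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split gave 1 gene by edgeR, as did 1 other (2 of 10 in all), and the highest other gave 1. For DESeq2 the real split was the 1 with the highest count, 561 against 164, and for lists the 1 with the highest count, 12 against 11. Both next highest counts came from setting control 1 and mutants 1 and 2 against the rest. That split also divides the libraries by reads that aligned more than once (40.3 to 47.8% against 60.1 to 68.3%). The lowest camera adjusted p in another split was 1.81e-06 (imprinted), 4.12e-05 (S-phase), 5.68e-05 (mesenchyme) and 0.0925 (p53). Every other split keeps more mutants on 1 side, so part of the genotype difference stays in it. Of the tested genes, 1521, 618 and 1262 were at 0 in mutants 1 to 3 and 464, 342 and 344 in controls 1 to 3, and why was not tested over all of them.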

Other observations

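All tests in this part were chosen after the results they bear on had been seen, except the test of Snrnp25. Outside the lists, several genes stood close to the edgeR threshold and were chosen after their values were seen. The linker histone gene H1f0, a mark of cells leaving the cycle, was at 68.5 ± 21.3 CPM in controls and 291 ± 32 CPM in mutants (SD, n = 3, adjusted p = 0.0877 by edgeR), and the cell cycle factor E2f2 at 278 ± 70.9 and 64.5 ± 28.2 CPM (adjusted p = 0.0977). Ptgr1, a reductase that detoxifies lipid aldehydes, was at 15.5 ± 8.77 and 221 ± 103 CPM (adjusted p = 0.0712), and the secreted stress-induced Stc2 at 3.62 ± 2.44 and 70.0 ± 16.3 CPM (adjusted p = 0.0975). In each of these, every mutant lay apart from every control.

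A pair of neighbours beside the alpha-globin genes was higher. Mpg, a DNA glycosylase gene (chromosome 11, 32226505 to 32232700), was at 14.7 ± 4.84 CPM in controls and 122 ± 34.6 CPM in mutants, and Rhbdf1 (32209585 to 32222300) at 49.8 ± 10.3 and 197 ± 53.7 CPM, with adjusted p of 0.0875 and 0.0977 by edgeR. A candidate explanation is that loss of CTCF opens these genes to the globin enhancers, which lie within the Nprl3 gene. It predicted a rise of the next gene outward, Snrnp25, whose log2 fold change was −0.36 (SE 0.68), at 70.2 ± 42.1 and 54.6 ± 32 CPM, and the bound set beforehand, a value plus 2 SE below 1, was just met (0.997). With RLE factors (−0.29) it was 1.06, and it was also above 1 with upper quartile factors or total counts, and without control replicate 2 or 3 or mutant replicate 1 or 3. Nprl3, within which Mpg lies on the opposite strand, was at 24.6 ± 5.68 and 23.2 ± 3.90 CPM. The hypothesis therefore stays open, as does a change limited to Mpg and Rhbdf1.

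The fall of S-phase and G2 and M-phase genes was set against a loss of erythroid cells from the sorts. That explanation needs the erythroid transcripts to fall as far. The score of all 21 erythroid genes differed by −0.74 (SE 0.17), that of the 7 with a mean CPM of at least 1000 by −0.28 (SE 0.16), the S-phase score by −1.29 (SE 0.25) and the G2 and M-phase score by −1.11 (SE 0.33). The S-phase score fell further than both, by 0.55 (SE 0.24) beside all erythroid genes and by 1.01 (SE 0.18) beside the abundant ones. The first difference is little over 2 SE with 3 libraries per group, and mutant replicate 3 lay close to the highest control in it (2.38 against 2.37). An equal fall of the whole erythroid list is therefore not excluded, though the abundant erythroid genes fell less than the S-phase genes. The G2 and M-phase score differed by 0.38 (SE 0.35) from all erythroid genes and by 0.83 (SE 0.28) from the abundant ones. For both cell cycle lists a loss of erythroid cells stays open. A trend of fold change with transcript length and GC content explained 2.65% of the variance. With it subtracted, the median of the 59 cell cycle genes was −0.997, against −0.99 before, so the trend fitted over all genes does not account for it. Its SE of 0.10 comes from resampling genes, and leaves out the spread between embryos and the correlation of genes. The genotype, a cell cycle arrest downstream of the p53 targets and a change in the maturity of the sorted cells stay open and were not tested.

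The rise of imprinted genes was set against a larger share of mesenchymal cells. The mesenchyme score without Dlk1 was 1.46 higher in mutants (SE 0.29), and with it as a term Ctcf itself had a log2 fold change of 0.81, so the fit had lost the genotype and the share of mesenchyme and the genotype cannot be told apart for these genes. The collagens Col1a1, Col3a1 and Col1a2, the most abundant members, stood at 3108, 1589 and 1064 CPM in mutants. A sort for GFP should remove cells without Cre history. With the length and GC trend subtracted, the imprinted median was 1.41 (SE 0.23, again from resampling genes), against 1.49 before. The trend fitted over all genes therefore does not account for it. H19 moved opposite to Igf2, and whether this reflects CTCF at their shared control region was not tested.

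Fxn had 142, 332 and 195 reads in the controls and 0 in each mutant. If mutant libraries lost low-level genes independently, then of 2339 genes within 1.5 times its control level, with 11.8, 2.61 and 7.23% at 0 in mutants 1 to 3, 0.518 would be at 0 in all 3 (upper 95% Poisson limit 2). The count was 10, Fxn included. The expected number gives all these genes the same chance of loss within a library. Genes that are lost more easily than others would exceed it even if libraries lost genes independently. Fxn was also known to be at 0 when the test was chosen. The test therefore cannot decide on independent loss, for the group or for any single gene. The others, chosen after their values were seen, include the mitochondrial peptidase Mipep, which processes imported proteins, and the blood genes Mpo and P2rx1. A shared loss of a blood cell type is an open explanation for part of them and was not tested, as is the genotype.

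Among the embryonic beta-globins, the ratio of Hbb-bh1 to Hbb-y was 22.7 ± 4.02% in controls and 8.55 ± 4.62% in mutants (SD, n = 3, two-sided exact permutation p = 0.1, the smallest this design allows). Since Hbb-bh1 is the earlier of the pair, more mature erythroid cells are a candidate explanation. It predicted a lower ratio of Hba-x to the adult alpha-globins, and the median was 57.2 in mutants (55.2 to 124) and 48.5 in controls (32.5 to 83.2), with an exact p of 0.5. The ranges overlap and reads of near-identical alpha-globin genes are uncertain, so the explanation stays open.

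Reads of sex-linked genes stood out in 2 mutant libraries. Mutant replicate 2 expressed Xist at 2631 CPM, as in a female embryo, and also held Y-linked genes at a sum of 15 CPM (105 reads), above the 2.23 CPM (20 reads) that was the higher of the 2 female controls. Mutant replicate 3, a male by its Y-linked sum of 193 CPM, held Xist at 20.5 CPM (95 reads), against 0.502 CPM (4 reads) in the 1 male control. The counts do not show whether these reads were carried over from other libraries or came from other cells. The same doubt holds for the sex taken for both libraries and for the Ctcf counts of mutant replicate 2 (18.1 CPM).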
